A study of Mus musculus with 6 samples.

How the data were processed

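Gene expression was measured in malignant epithelial cells grown as a short-term explant from the pancreatic carcinoma of a mouse of the KPC-Brca1 model. The 6 samples were 3 untreated replicate plates and 3 plates treated for 48 h with 0.5 µM decitabine (5-aza-2′-deoxycytidine, DAC), a cytidine analog that traps DNA methyltransferases once it is built into DNA. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared with an Ambion MessageAmp kit for Illumina bead arrays. The scanner software, the steps before export, the slides and the statistics were not given in the sources used here. The labels speak of replicate plates of an explant culture and name no separate tumours. The p-values therefore measure the spread between these plates, which may be technical, and not between animals.

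The deposited table that is not normalized covers 45281 probes. Per the file headers, it holds for each probe and array the mean bead intensity, the standard error of the beads, the number of beads and a detection p-value. The headers do not say what the detection p-value was computed against, and negative control beads were assumed here. These intensities are linear, were neither background-subtracted nor scaled between arrays, and had no value below 0. The authors also deposited a second table of linear intensity values. Its lowest value was -17.9, 31.8% of its values lay below 0, and the sorted values of all 6 columns differed from those of the first by a median of at most 0.1, as quantile normalization after background subtraction would leave them. The median of each column was 7.0 or 7.1, and how its background was set stays unknown. Its probe identifiers are not paired with gene names or with the other table in the sources used here. Of 200 of its entries, 199 had a probe in the first table whose rank on every array was within 1 rank, against 1 with the first 2 arrays exchanged. It therefore served only for counts of unnamed probes.

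Mean intensity per array was 460, 333.5 and 340.4 for untreated replicates 1 to 3 and 359.1, 360.7 and 313.2 for DAC replicates 1 to 3. The median number of beads per probe was 44 on 5 arrays and 45 on DAC replicate 3. Between 43.9% and 47.4% of probes had a detection p under 0.05. The number of arrays limits the precision.

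Background was corrected in R 4.3.3 with limma 3.58.1 by the neqc method, which here inferred the negative controls from the detection p-values, with an offset of 16, quantile normalization and log2. Probes were kept when their detection p was under 0.05 on at least 3 of the 6 arrays, which left 21415. Gene names on the array are old, so its 30854 names were matched to current RefSeq symbols (assembly GRCm38.p6, used for names and gene order only). Of these, 16223 matched a symbol, 5684 matched a synonym of a single gene and 8947 matched neither and kept the name of the array. Each gene was represented by its probe with the highest mean over all 6 arrays, which gave 14154 genes, 11314 of them with a RefSeq symbol. Of 845 changed genes with several probes, 310 had all probes called the same way, and 5 had a probe that changed the other way. In most of the 845, at least 1 probe was therefore not called. Among these were Uhrf1, Tk1, Spint1 and Slc22a17, each with 1 of 2 probes called. Probes of close relatives, such as the H2-Q, Gbp, Oas1, Tuba3, Psg and Prl genes, can bind each other's transcripts, and values within these families are uncertain in that respect.

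Treated and untreated arrays were compared gene by gene with limma's lmFit and eBayes, without covariates, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from this limma fit. Values are given as log2 fold change, DAC minus untreated, ± standard error (SE), or as mean log2 signal ± standard deviation (SD), with n = 3 per group. A gene with no probe detected on any array of a group has only a bound there. Its fold is written "at least", and was computed against the higher of the probe's own value and the lowest value of any detected probe on each array, which was 4.76 to 4.93 on the log2 scale. Genes were also counted as detected only after DAC when no probe was detected on any untreated array and a probe was detected on all 3 DAC arrays, and the reverse.

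The 21 gene lists, the comparison, the filters, the rule for named genes and the alternatives were fixed before the data were examined, with the exceptions stated below. Among genes with a current RefSeq symbol, the rule took the 10 detected on all 6 arrays with the largest rise and the 10 with the largest fall, the 10 seen only with DAC with the largest bound and up to 5 of the reverse kind. All of these needed an adjusted p under 0.05, and those detected on all 6 arrays also needed groups without overlap. The rule also took the 4 measured members of each list with the lowest adjusted p, and 12 genes chosen in advance. It gave 116 different genes, not all of which are reported here, and other names given below were chosen after their values were seen or are members of a list. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists, and again with an estimated correlation and with fry.

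The steps were tested on data simulated for this comparison, with 200 genes changed among 15477. Of 67 genes changed by 0.5 on the log2 scale, 2.99% were called in the right direction, against 49.3% of 67 genes changed by 1 and 80.3% of 66 genes changed by 2. Of all calls, 4.35% were unchanged genes, and the median estimate for a true size of 2 was 1.78. A list of planted genes was called, and 0 of 20 random lists were. The simulated noise was independent between genes and between arrays, and the 200 changes were planted in random directions. Shifts shared by many genes of 1 array, and correlation within lists, were not simulated. Error rates and power in the real data can therefore differ from these values.

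Alternatives were no background correction, a normexp correction with an offset of 50, median scaling, cyclic loess, no filter, 2 stricter filters, the mean of a gene's probes, a variance trend, the replicate number as a block, and leaving out each array in turn. Fits without an array kept the probes of the full set, a choice made after a first version, which filtered on 5 arrays and lost genes seen only with DAC. After the data were seen, a fit with untreated replicates 2 and 3 averaged into 1 sample was added. A set of 7 further gene lists, used among the closing observations, was also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.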

Results

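Illumina bead arrays measured RNA levels in cultured malignant epithelial cells of a KPC-Brca1 mouse pancreatic carcinoma, with 3 untreated plates and 3 plates kept for 48 h in 0.5 µM DAC. The title of the series asks which genes DAC activates in these cells. Between 19890 and 21462 of 45281 probes were detected per array, and 14154 genes were tested. The arrays of untreated replicates 2 and 3 lay close together. Their median squared difference was 1.70 times the bead variance, against 3.59 to 27.1 for the other pairs within a group. They were kept as separate samples as labelled, although a ratio to bead noise does not tell whether 2 arrays came from separate plates. Untreated replicate 1 stood apart from both, at 23.1 and 27.1 times the bead variance, and had the highest mean intensity of the 6 arrays. By that ratio it lay nearer to DAC replicates 2 and 3, at 15.96 and 16.32. Its log2 values correlated more with untreated replicates 2 and 3 (r = 0.982 and 0.981) than with the DAC replicates (r = 0.966 to 0.971).

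**Figure D1:**
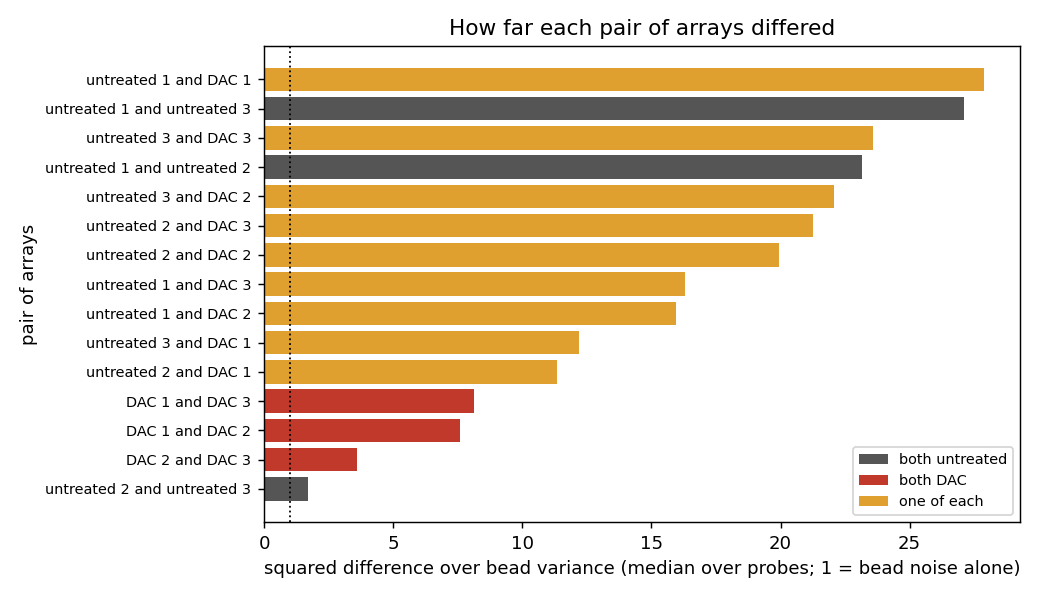
Median over probes of the squared difference between the signals of 2 arrays, divided by its bead variance, for each pair of the 6 arrays. The dotted line at 1 marks bead noise alone. The pair of untreated replicates 2 and 3 had the lowest ratio, 1.70, and pairs with untreated replicate 1 reached 27.9.

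Genes of the germ line, interferon-stimulated genes, MHC class I genes and cell cycle genes rose after DAC, and large falls were few. Among genes with a current symbol detected on all 6 arrays, the largest rises were those of Rhox5, a homeobox gene of the reproductive tract and placenta, at 4.81 ± 0.26 (log2, SE, n = 3 per group), and of Psg23, a pregnancy-specific glycoprotein of the placenta, at 4.38 ± 0.10. Gbp3 (4.00 ± 0.11), Mx2 (3.68 ± 0.15), Gbp2 (3.62 ± 0.13), Oasl2 (3.56 ± 0.18), Gbp2b (3.52 ± 0.16), Irf7 (3.48 ± 0.13) and Cmpk2 (3.48 ± 0.17), which interferons are known to induce, were also among the 10 largest of these, as was the transporter gene Slc47a1 (3.70 ± 0.15). Adjusted p for these 10 genes lay between 1.68e-07 and 1.26e-05 (limma, Benjamini-Hochberg). All 3 DAC values lay above all 3 untreated values, as the rule that named them required.

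Among genes with a current symbol detected on all 6 arrays, the largest falls were smaller. The gene of the matrix glycoprotein thrombospondin 1, Thbs1, fell by 1.74 ± 0.39 (adjusted p = 0.0188, limma), from 8.10 ± 0.53 to 6.35 ± 0.77 (log2 signal, SD, n = 3). That call did not hold without untreated replicate 2, untreated replicate 3 or DAC replicate 2, or without the filter on dim probes. The phosphatase gene Acp1 fell by 1.64 ± 0.20, the adenylate kinase gene Ak5 by 1.46 ± 0.11, Cdh13, a cadherin, by 1.40 ± 0.11, and Aldoc, a glycolytic aldolase, fell by 1.37 ± 0.11. Gm5148, Tmem158, Pdzk1ip1, Pitpnc1 and Slc22a17 completed the 10 largest of these falls, with log2 fold changes from -1.42 to -1.31.

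In all, 2450 genes changed, 1429 upward and 1021 downward. With the replicate number as a block 874 changed, 697 upward and 177 downward, and with median scaling 907 rose. By fitted values, 506 genes rose and 57 fell at least 2-fold, against 354 and 53 with detection required on all 6 arrays. All counts by size of fold, here and below, take a gene not detected in a group at its fitted value, which may exceed its bound. At least 4-fold by fitted value, 123 rose and 2 fell. Those 2, named after their values were seen, were Vip, at -2.39 ± 0.18 and detected on 1 of 3 DAC arrays, and A230021I18RIK, which has no current symbol and was at least 3.33-fold lower with DAC. The groups were fully separated in 36.2% of the genes tested, where chance gives 10%. Of the changed genes 58.3% had risen, against 48.4% with median scaling, which moved the median log2 fold change of all genes from -0.02 to -0.12, and 67.3% with cyclic loess. Without untreated replicates 1, 2 and 3 and DAC replicates 1, 2 and 3 in turn, 4716, 1274, 1378, 1901, 1225 and 1367 genes changed, of which 2537, 901, 947, 1236, 885 and 923 rose and 2179, 373, 431, 665, 340 and 444 fell. By fitted value, rises of at least 2-fold numbered 474 to 590 across those fits, 322 without background correction and 282 with an offset of 50. Falls of at least 2-fold by fitted value numbered 102 without untreated replicate 1, 16 without background correction and 12 with an offset of 50. They numbered 120 with median scaling and 36 with cyclic loess. With untreated replicates 2 and 3 averaged into 1 sample, a fit chosen after the data were seen, 1320 genes changed, 929 upward and 391 downward.

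Many genes were seen only in treated plates. No probe of 279 genes was detected on any untreated array while a probe was detected on all 3 DAC arrays, and the reverse held for 53 genes. Among those with a current symbol, the largest bounds were those of Cfap70, a gene of cilia, at least 34.4-fold higher with DAC, and of the germ cell genes Taf7l (at least 21.5-fold), Tex19.1 (at least 20.5-fold) and Dazl (at least 20.1-fold). Hamp2, a hepcidin gene, was at least 13.9-fold higher and the chemokine gene Ccl4 at least 11.5-fold. Trim30a, Tex19.2, Ddx60 and the keratin gene Krt16 followed with bounds from 5.32 to 6.88. Adjusted p for these 10 genes lay between 1.60e-07 and 3.69e-05 (limma). In the reverse direction, among genes with a current symbol, the largest bounds were small, with Syt5 at least 1.47-fold lower and Crabp1 at least 1.46-fold lower with DAC, the latter call being lost without DAC replicate 2. The 53 genes became 186 without untreated replicate 1, 83 without untreated replicate 3, and 100 and 88 without DAC replicates 1 and 2, and 26 at a detection p under 0.01.

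Germ-line genes, normally silent in epithelium, formed the list with the largest single rises. Of 64 list genes on the array, 27 had no probe detected on any array and 28 were measured. Of these 28, 25 rose and 0 fell (26 adjusted over the list alone). The median log2 fold change was 1.63, or 1.28 with 19 members, not detected on any untreated array, at their lower bound, and the list stood above other genes (adjusted p = 1.33e-26, camera; adjusted p = 0.0155 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, went from 4.54 ± 0.08, not detected, to 9.15 ± 0.12 (log2 signal, SD, n = 3), and Taf7l from 4.38 ± 0.07, not detected, to 9.25 ± 0.05. The 19 members not detected on any untreated array passed the filter only through the DAC arrays, which favours rises. Without the filter on dim probes, 29 of all 64 rose and 0 fell, with a median of 0.21. With detection required on all 6 arrays, 8 members remained, of which 6 rose and 0 fell (adjusted p = 5.90e-08, camera). Asz1, a component of the piRNA pathway, was detected on all arrays and rose by 3.44 ± 0.12. Tex101, Tdrd1 and Brdt did not pass, at 0.41, 0.21 and -0.01.

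Interferon-stimulated genes rose almost throughout. Of 45 measured members 44 rose and 0 fell (44 adjusted over the list alone), with a median log2 fold change of 1.95 (adjusted p = 2.53e-43, camera; adjusted p = 0.0104 with an estimated correlation). Ifit3 rose by 3.40 ± 0.11 (adjusted p = 9.17e-07, limma), from 9.33 ± 0.05 to 12.73 ± 0.10 (log2 signal, SD, n = 3), and Oas1g, of the oligoadenylate synthetase family, by 3.07 ± 0.11. Ifi27 was the member that did not pass, at 0.01.

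MHC class I antigen presentation genes rose with them. Of 22 measured, 19 rose and 0 fell (19 adjusted over the list alone), with a median of 1.24 (adjusted p = 1.74e-14, camera; adjusted p = 0.0104 with an estimated correlation). The immunoproteasome subunit gene Psmb8 rose by 2.87 ± 0.14, the peptide transporter gene Tap1 by 2.35 ± 0.16, H2-Q6 by 1.90 ± 0.12 and H2-Q8 by 1.84 ± 0.13. Pdia3, H2-Q1 and Calr did not pass, with values from 0.02 to 0.10.

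Chemokine and cytokine genes rose in part. Of 22 measured, 15 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.82, or 0.66 with 3 members at their bound. The list stood above other genes by camera (adjusted p = 2.31e-08) but not with an estimated correlation (adjusted p = 0.143 with an estimated correlation). Cxcl10, an interferon-induced chemokine, rose by 2.90 ± 0.15, Csf2 by 2.62 ± 0.21, Cxcl1 by 2.28 ± 0.18 and Ccl2 by 1.34 ± 0.11. Cxcl15 was the member that fell, by 0.97.

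Cell cycle genes rose in both lists. Of 28 measured genes of S phase and DNA replication, 23 rose and 0 fell (28 adjusted over the list alone), with a median of 0.87 (adjusted p = 5.07e-17, camera; adjusted p = 0.0113 with an estimated correlation). Cdc6, which loads the replicative helicase, rose by 1.80 ± 0.17, Mcm5, a helicase subunit, by 1.68 ± 0.12, Mcm10 by 1.63 ± 0.17 and Cdc45 by 1.27 ± 0.12. Of 24 genes of G2 and mitosis, 21 rose and 0 fell (23 adjusted over the list alone), with a median of 0.94 (adjusted p = 6.42e-17, camera; adjusted p = 0.0104 with an estimated correlation). Birc5 rose by 1.37 ± 0.11, Foxm1 by 1.36 ± 0.13, Cdc20 by 1.25 ± 0.13 and the proliferation marker Mki67 by 1.20 ± 0.11. Without untreated replicate 1, which stood apart, 26 S phase and 23 mitotic genes rose, and so did 44 interferon-stimulated, 19 MHC class I and 25 germ-line genes. When any other array was left out, 17 to 20 S phase, 19 to 21 mitotic, 41 to 44 interferon-stimulated, 14 or 15 MHC class I and 25 germ-line genes rose. With the replicate number as a block, 13 S phase, 17 mitotic, 42 interferon-stimulated, 14 MHC class I and 24 germ-line genes rose.

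**Figure D2:**
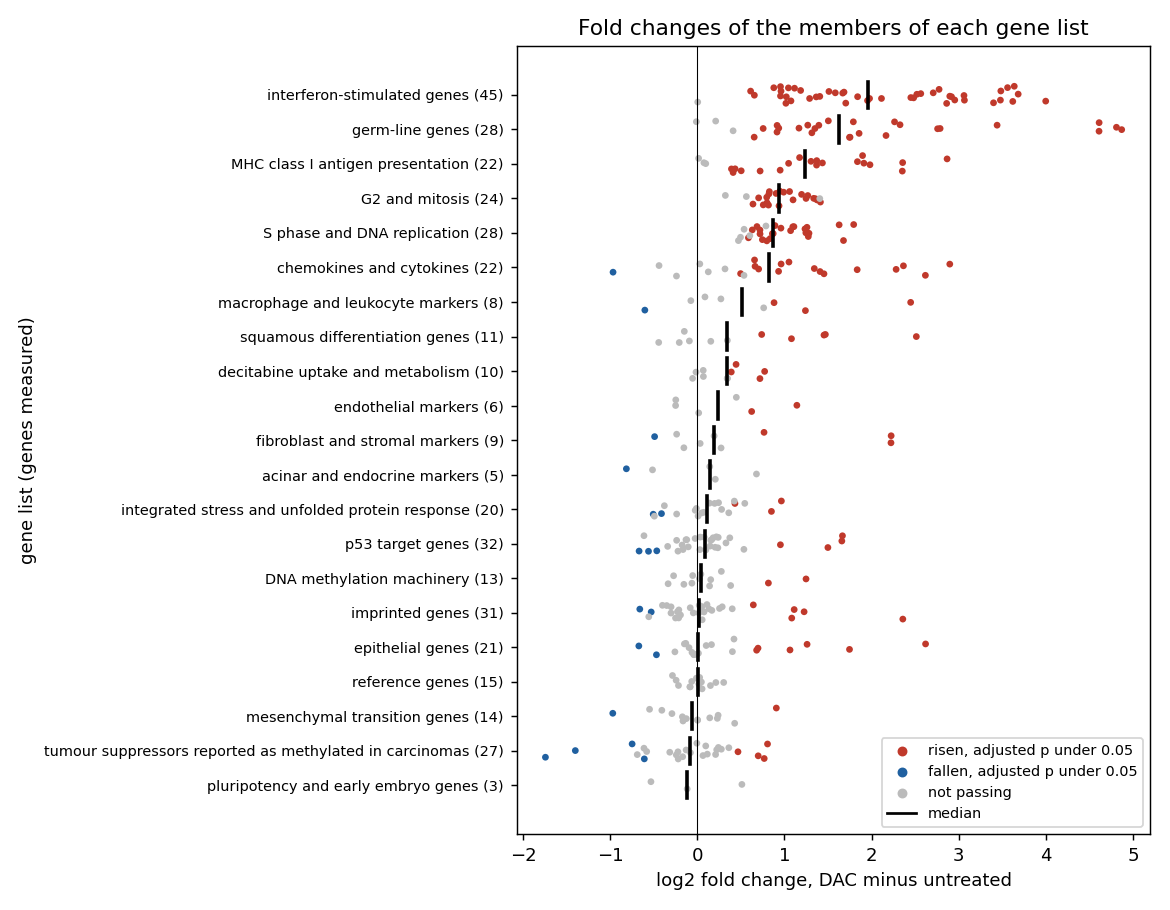
Log2 fold change of each measured member of the 21 gene lists, DAC minus untreated, with 1 point per gene and the number measured in brackets. Red points rose and blue points fell at an adjusted p under 0.05 (limma), grey points did not pass, and black bars are medians of fitted values, which for genes not detected in a group are no bounds. In the interferon-stimulated list 44 of 45 points are red, and in the reference list all 15 are grey.

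The p53 targets and the DNA methylation genes showed single changes, and neither list stood above other genes by camera. By fry, which does not compare a list with other genes, both were higher with DAC (adjusted p = 0.0158 and adjusted p = 0.0291). Cdkn1a, the gene of the cell cycle inhibitor p21, rose from 8.15 ± 0.18 to 9.65 ± 0.06 (log2 signal, SD, n = 3). The death receptor gene Fas rose by 1.66 ± 0.15, Gtse1 by 1.67 ± 0.17 and Plk2 by 0.95 ± 0.13. Of 32 p53 targets 4 rose and 3 fell (adjusted p = 0.357, camera), with the same numbers adjusted over the list alone. The 3 falls became 5 without untreated replicate 1, 0 without DAC replicate 2 and 1 without any other array. Uhrf1, which recruits the maintenance methyltransferase to DNA, rose by 1.25 ± 0.16 and the gene of that enzyme, Dnmt1, by 0.82 ± 0.15. Dnmt1 was not past the threshold with median scaling or without DAC replicate 2. They were 2 of 13 DNA methylation genes (2 adjusted over the list alone), and 0 fell, or 1 without untreated replicate 1 (adjusted p = 0.421, camera). Only 1 of the 13 rose with the replicate number as a block. Dnmt3b did not pass, at 0.14 ± 0.18, and no probe of Dnmt3a was detected on any array.

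Genes of decitabine uptake and metabolism stood slightly above other genes. Of 10 measured, 4 rose and 0 fell (4 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0181, camera; adjusted p = 0.143 with an estimated correlation). Samhd1, a deoxynucleotide triphosphate hydrolase, rose by 0.77 ± 0.11 and the thymidine kinase gene Tk1 by 0.72 ± 0.14. Cda, the gene of the cytidine deaminase that inactivates decitabine, rose by 0.39 ± 0.11, and Nme1 by 0.45 ± 0.12, and both calls were lost with median scaling and when any 1 array other than untreated replicate 1 was left out. Only 1 of the 10 rose with the replicate number as a block. The call on the list was lost with median scaling (adjusted p = 0.0657), without untreated replicate 1 (adjusted p = 0.0948) and without DAC replicate 1 (adjusted p = 0.0640).

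Epithelial genes moved both ways. Of 21 measured, 6 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.108, camera). The transcription factor gene Grhl2 rose by 2.62 ± 0.16 (detected on 2 of 3 untreated arrays), the claudin gene Cldn4 by 1.75 ± 0.12, Elf3 by 1.26 ± 0.16 and Spint1 by 1.06 ± 0.15, while Cdh1 did not pass, at 0.16 ± 0.14. The 2 falls became 1 without untreated replicate 2 or 3 or DAC replicate 2 or 3. Of 14 mesenchymal transition genes, 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.818, camera). These were Lox, at least 1.54-fold higher with DAC, and the fibronectin gene Fn1, which fell by 0.97 ± 0.20. The call on Fn1 was lost when untreated replicate 2 or 3 or DAC replicate 2 or 3 was left out, and with the replicate number as a block. Without untreated replicate 1, 2 mesenchymal transition genes rose and 3 fell. Vim did not pass, at -0.41 ± 0.21. Of 11 squamous differentiation genes 5 rose and 0 fell (5 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0134, camera; adjusted p = 0.356 with an estimated correlation). Krt16 was at least 5.32-fold higher, Krt13 rose by 1.47 ± 0.14 and Sprr1b by 1.45 ± 0.13, and among members detected on all 6 arrays the median was -0.09 (adjusted p = 0.665, camera).

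Markers of other cell types that an explant could hold were measured in the same way. Of 9 fibroblast and stromal markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.286, camera), with Acta2 up by 2.23 ± 0.23 and Col1a1 by 2.22 ± 0.25, and 0 fell when any array other than untreated replicate 1 was left out. Of 8 macrophage and leukocyte markers 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.0397, camera; adjusted p = 0.354 with an estimated correlation). Laptm5 was at least 3.93-fold higher, Fcgr3 rose by 1.24 ± 0.13 and Cd14 fell by 0.60 ± 0.11, and the call on the list was lost with an offset of 50, with both stricter filters, and without untreated replicate 1 or DAC replicate 1. Of 6 endothelial markers 2 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.286, camera), among them Esam by 1.14 ± 0.14. That count was 1 without untreated replicate 2 or 3 or DAC replicate 2 or 3, and 1 endothelial marker fell without untreated replicate 1. Of 5 acinar and endocrine markers 0 rose and 1 fell (1 and 2 adjusted over the list alone; adjusted p = 0.942, camera), with a median of 0.14, a mean of -0.06 and a downward sign by camera. Of these 5, 2 fell without untreated replicate 1, 0 fell without untreated replicate 3, DAC replicate 1 or DAC replicate 2, and 1 rose without untreated replicate 3 or DAC replicate 1.

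The remaining lists did not stand apart by camera. Of 31 imprinted genes, expressed from a single parental allele, 5 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.692, camera), with Dlk1 up by 2.36 ± 0.15 and Cdkn1c by 1.23 ± 0.15, while H19 did not pass, at -0.30 ± 0.12. The 2 falls became 5 without untreated replicate 1, 1 without untreated replicate 2 and 0 without untreated replicate 3 or DAC replicate 2 or 3. Of 27 tumour suppressors reported as methylated in carcinomas, 4 rose and 4 fell (4 and 6 adjusted over the list alone; adjusted p = 0.692, camera), with Uchl1 up by 0.81 ± 0.13 and Rarb, a retinoic acid receptor gene, down, at -0.75 ± 0.13. Without untreated replicate 1, 5 rose and 6 fell, without untreated replicate 2 or DAC replicate 2, 2 and 2, and without DAC replicate 3, 2 and 3. Of 20 genes of the integrated stress and unfolded protein response, 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.309, camera), with Ddit3 up by 0.97 ± 0.13 and Atf3 by 0.85 ± 0.14. Without untreated replicate 1, 5 of the 20 rose and 3 fell. Without any other array 2 rose, and 1 fell without DAC replicate 3 and 0 without each of the rest. None of 3 measured pluripotency genes passed, or 1 without untreated replicate 1 (adjusted p = 0.942, camera). Of 15 reference genes 0 passed, also adjusted over the list alone (adjusted p = 0.928, camera), with a median of 0.01, a mean of -0.01 and a downward sign by camera, and without untreated replicate 1, 1 rose and 1 fell. Actb was at 0.21 ± 0.17, with the opposite sign without untreated replicate 1, and Gapdh at 0.05 ± 0.11, with the opposite sign under median scaling. By camera, 9 of 21 lists stood higher with DAC and 0 lower, with 5 and 0 by an estimated correlation, 15 and 0 by fry, and 0 lower at an unadjusted p under 0.05.

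**Figure D3:**
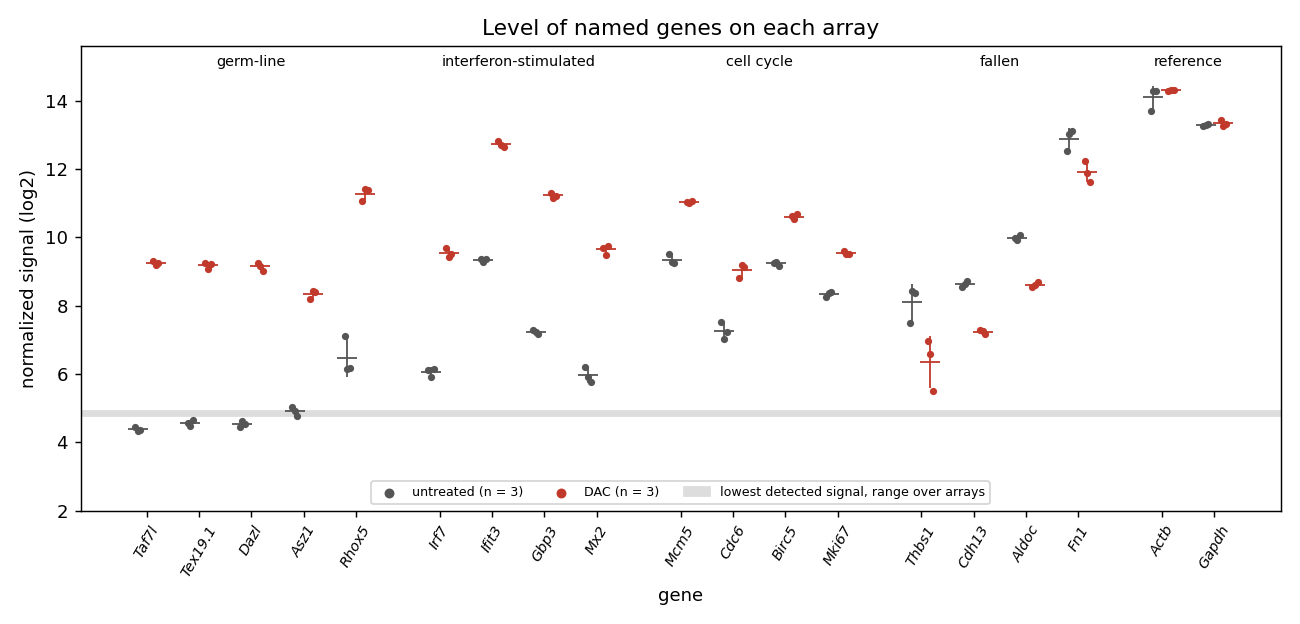
Normalized log2 signal of named genes on each array, untreated in grey and DAC in red, n = 3 each, with the mean as a horizontal bar and the SD as a vertical line. The grey band is the lowest signal of a detected probe over the 6 arrays, 4.76 to 4.93. Untreated Taf7l, Tex19.1 and Dazl lie below the band, and their DAC values lie near 9.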

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

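The fit that averages untreated replicates 2 and 3 into 1 sample was chosen after the data were seen, and the fits without an array kept the probes of the full set. Without background correction 322 genes rose and 16 fell at least 2-fold, and with an offset of 50, 282 and 12. Median scaling gave 907 risen genes and 120 fallen at least 2-fold, and cyclic loess gave 36 fallen at least 2-fold. The causes of these differences were not tested. Leaving out 1 array in turn gave 1225 to 4716 changed genes, 885 to 2537 risen, 340 to 2179 fallen, 474 to 590 risen at least 2-fold, 47 to 102 fallen at least 2-fold, 7 to 9 lists higher, 320 to 368 genes detected only after DAC and 74 to 186 only without it. With untreated replicates 2 and 3 averaged, 1320 genes changed, 929 upward and 391 downward, from fewer samples. At a detection p under 0.01, 26 genes were detected only without DAC and 340 only after it. An estimated correlation left 5 lists higher and fry gave 15, since fry does not compare a list with other genes. Deviations of plates of the same replicate number correlated at -0.61, -0.11 and -0.48, and no untreated plate correlated best with its own number. The correlations of untreated replicates 2 and 3 were close to each other and opposite in sign to those of untreated replicate 1. They are thus not separate evidence, and cannot exclude that plates were paired. With the replicate number as a block, 874 genes changed, 697 upward and 177 downward, from fewer residual degrees of freedom. The other filters, the mean of a gene's probes and the variance trend moved none of these counts by over 1.5 times. Of 95 named genes that were called, 76 kept the call in every alternative that gave them a value, and 79 did so apart from the block. Of the 75 with a value in every alternative, 60 kept it. Of the named genes that were called, none turned its sign, and no called list turned its direction by camera. The median of the squamous list was nevertheless -0.09 among probes detected on all 6 arrays. In the deposited normalized table, 3100 probes changed, 1687 upward and 1413 downward, against 3202, 1785 and 1417 in the first table. It was not run by gene, as its probes come without names, and slide as a block was not run because the files used here give no slides. Signal over background limits dim genes, since at most 47.4% of probes were detected on each array.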

Other observations

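The lists and genes of this paragraph and the next were chosen after the data were seen, so their p-values partly restate it. Of 16 measured homologous recombination genes 12 rose and 0 fell (adjusted p = 2.92e-07, camera; adjusted p = 0.0406 with an estimated correlation). Bard1 rose by 1.26 ± 0.12 and Brip1 by 1.24 ± 0.16 (log2, SE, n = 3 per group). The probe of Brca1 rose by 0.87 ± 0.16, and whether it lies outside the part altered in this model was not given in the sources used here. Of 22 placental genes on the array 14 had no probe detected on any array, and of the 7 measured 5 rose and 0 fell (adjusted p = 6.74e-05, camera; adjusted p = 0.0406 with an estimated correlation), with Prl2c2 up by 1.37 ± 0.11 and Plac1 by 1.09 ± 0.15. Psg23, whose rise was already known, is a member. Without it 4 of 6 rose (adjusted p = 0.00157, camera), and the call on the list was lost with an estimated correlation (adjusted p = 0.0645 with an estimated correlation). Of 10 nucleic acid sensor genes 7 rose and 1 fell (adjusted p = 0.000287, camera), a call on the list that was lost with an estimated correlation (adjusted p = 0.114 with an estimated correlation), with Dhx58 up by 2.92 ± 0.14, Eif2ak2 by 1.70 ± 0.12 and Sting1 at -0.65 ± 0.13. Of these, 4 also belong to a list fixed earlier.

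Of 20 cholesterol synthesis genes 8 fell and 0 rose (adjusted p = 6.74e-05, camera), a call on the list that was lost with an estimated correlation (adjusted p = 0.0645 with an estimated correlation). Among those that fell were Mvd at -0.94 ± 0.13 and Cyp51 at -0.70 ± 0.15. Of 23 glycolysis and hypoxia genes 7 fell and 0 rose (adjusted p = 0.000561, camera; adjusted p = 0.0406 with an estimated correlation), with Pdk1 at -0.82 ± 0.12 and Vegfa at -0.56 ± 0.13. Of 18 interferon genes on the array 12 had no probe detected on any array, and the 3 measured did not pass (adjusted p = 0.678, camera). Ifnb1 was detected on 2 DAC arrays and 0 untreated arrays. Of 9 MHC class II genes 5 had no probe detected on any array and 1 of 2 measured rose (adjusted p = 0.335, camera). The probe that the array names IAP, as intracisternal A-particle retroelements are known, rose by 3.25 ± 0.14, from 10.98 ± 0.18 to 14.23 ± 0.15 (log2 signal, SD, n = 3). Among features detected on all 6 arrays, the largest rise was that of LOC280487, which has no current symbol in the table used, at 6.69 ± 0.13. LOC386135, also without a current symbol and not detected on any untreated array, was at least 71.2-fold higher with DAC.

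For the patterns weighed next, the tests of leukocytes, of stromal cells and of interferon-stimulated genes without untreated replicate 1 were chosen after the result was seen. Interferon-stimulated genes rose with DAC, 44 of 45. Leukocytes in the treated plates would bring their abundant transcripts. Of 8 abundant leukocyte markers, Ptprc, Tyrobp, Lyz2 and Cd52 among them, 0 were detected on any array. The 8 were chosen after the data were seen, and none had passed the filter, which any gene detected on all 3 DAC arrays passes. Their 0 may therefore follow from the choice and does not decide the question. Of all 23 leukocyte list genes on the array, 12 had no probe detected on any array. Other leukocyte markers did go with the interferon-stimulated genes. Laptm5 was at least 3.93-fold higher and Fcgr3 (1.24) and Cd53 (0.88) rose, both detected on all 3 untreated arrays, and the leukocyte list stood higher (adjusted p = 0.0397, camera; adjusted p = 0.354 with an estimated correlation). Quantile normalization was argued against as the sole cause, since 44 members rose with median scaling. Untreated replicate 1 had a mean list signal of 7.94, against 7.79 in each of untreated replicates 2 and 3 and 9.90 to 9.95 in the DAC plates. Without that array the median log2 fold change was 1.80, against 1.95 with all arrays. By mean signal it lay nearer to the DAC plates, so the 44 members that rose without that array do not test it as a cause. Slides and days of handling are not given in the files used here, so no batch was tested.

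Cell cycle genes rose with DAC, 44 of 52 in both lists. With median scaling 38 rose, which argues against quantile normalization as the whole cause. Untreated replicate 1 had a mean S phase signal of 8.32, against 8.15 and 8.17 in untreated replicates 2 and 3. For G2 and mitosis it was 8.34, against 8.29 and 8.30. Without this array the median log2 fold change was 0.85 for S phase, against 0.87 with all arrays, and 1.01 for G2 and mitosis, against 0.94. By the mean signals it lay nearer to the DAC arrays, so leaving it out widens the difference between those means. The 49 genes that rose without it therefore do not test it as a cause. A difference between plates in density or growth stays open, and no value here tests that.

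Col1a1 and Acta2 rose by 2.22 and 2.23. Stromal cells in the treated plates could raise other fibroblast markers too, and the median of the other 7 measured was 0.033, from -0.49 to 0.77. Markers already high in untreated plates, such as Fbln2 at 12.62 (log2 signal), could hide a small stromal share, so this median does not exclude it. Of 22 such markers on the array 12 had no probe detected on any array, Col1a2, Col3a1 and Dcn among them, and 9 were detected on all 6 arrays, untreated plates included. What raised both genes stays open.

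Neighbours were counted in the order of the 11314 tested genes with a current symbol, so genes that were not measured can lie between 2 neighbours. Genes risen at least 2-fold were neighbours in this sense in 29 pairs of different families, against a mean of 14.6 in 10000 permutations (p = 2e-04, permutation test). With members of the interferon-stimulated, germ-line and MHC class I lists left out there were 16 pairs, against a mean of 10.2 (p = 0.0499, permutation test). This second p was borderline, within the sampling error of the permutations around 0.05, and was not taken as a call; that margin was set after it was seen. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2450 changed genes, and the highest other split 0, with 1 of 10 splits as large as the real. It gave 563 genes changed at least 2-fold, against 0, and 9 lists apart from other genes, against 7. Every other split mixed treated and untreated arrays in each group, so the treatment difference added to the spread within groups. Their counts therefore do not show what chance alone would give.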
